A study of Rattus norvegicus with 8 samples.

How the data were processed

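The series holds 8 arrays of total RNA from rat left ventricle, labelled with biotin and hybridised by the standard Affymetrix protocol, per the labels' protocols. Groups were taken from the labels: 3 placebo and 5 ILPD samples. The values as deposited are on a log2 scale, which was settled from their range (about 5 to 15). Array medians lay between 7.08 and 7.14 in placebo and between 7.16 and 7.20 in ILPD. The method by which the authors normalized the log2 values is not given in the sources used here; the submitters' processing notes name R 2.14.2. No signal of background or detection was used here, so no probe set was called undetected, and no column marked control probe sets, so all 28826 were tested.

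Gene names came from the platform annotation supplied with the values, updated through gene IDs in a RefSeq gene table of assembly GRCr8. Of the probe sets, 15209 had 1 gene symbol, 306 had several and 13311 had none here, and 15178 of the first kind matched the RefSeq table by gene ID. A probe set with several symbols was not named. The named probe sets covered 14497 genes, and where a gene had several, the one with the highest mean over all arrays stood for it. Of 9 genes with several probe sets, among 99 taken from the naming rule, 1 (Mcl1) had probe sets of opposite sign. No genome coordinates are given, since the build behind the array design is not the one of the table.

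Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, no covariates, no pseudocount since values were already logged), two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Gene lists were tested with camera, with a preset correlation of 0.01 between genes and at least 5 measured members, adjusted over 42 lists, of which 14 held cell type markers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and no overlap between groups, the leading and the called members of each list, and a short set of genes of prior interest.

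The test was checked on simulated data of 28826 probe sets with 200 changed in each of 5 runs of this comparison. It recovered 86% of 1.5-fold and 97.2% of 2-fold changes, and 5.66% of the calls were false. The simulated noise was normal, independent between probe sets and drawn from limma's own fitted variances, without intensity-dependent shifts. A share of false calls near the threshold was therefore built in. Camera called the shifted list in 5 of 5 runs and 0 of 205 unchanged lists; genes were drawn independently there, unlike in tissue.

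The alternatives were an intensity trend with a robust prior, a further quantile normalization, a filter on the dimmest 40% of probe sets, array weights, the replicate number as a block, looser or fold-based thresholds, camera with an estimated correlation, fry, the mean of a gene's probe sets, and leaving out each array in turn. Cyclic loess normalization and the removal of a block of 1574 probe sets without names were chosen after seeing the data. The log-scale alternative for linear values was not needed.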

Results

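Gene expression was measured with Affymetrix arrays in the left ventricle of female rats in late pregnancy. All hearts had undergone ischemia, the interruption of blood supply, followed by reperfusion. Reperfusion came with a vehicle in 3 samples (placebo) and with the treatment the labels call ILPD in 5 samples, given as a single bolus of 5 mg/kg. The design text of the series, from which that dose and its unit are taken as stated, abbreviates the treatment as ITLD; that both abbreviations stand for 1 treatment is assumed. The title of the series speaks of Intralipid, a lipid emulsion given into a vein, and of protection of the heart. The comparison therefore asks which transcripts differed between treated and vehicle hearts after the same injury. Hearts without ischemia were not analysed here. The labels number the samples as replicates and do not say that each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical. Each array gave a log2 value for 28826 probe sets, with array medians between 7.08 and 7.20, and the number of arrays limits the precision. Over all probe sets, arrays of the same group correlated at 0.991 to 0.995 and arrays of different groups at 0.989 to 0.993.

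The 2 groups separated on the first principal component, which held 34.2% of the variance. Placebo arrays scored between -19.3 and -17.4 on it and ILPD arrays between 4.59 and 14.1. The second component, with 19.0%, spread the ILPD arrays from -15.6 to 20.6. In limma's test, 811 probe sets passed an adjusted p of 0.05, of which 564 were higher and 247 lower in ILPD. These covered 338 named genes that rose and 173 that fell. A change of at least 1.5-fold was seen for 160 of the higher and 57 of the lower probe sets, and of at least 2-fold for 23 and 19. The number of calls depended on single arrays. It was 172 without placebo array 2, 241 without placebo array 3 and 385 without placebo array 1. It was 382 without ILPD array 2, 500 without ILPD array 3 and 459 without ILPD array 4. Without ILPD array 1 it was 817, and without ILPD array 5 it was 975. Leaving out an array also lowers the sample number. For single genes, an adjusted p given below as a highest value ("up to" or "reaching") is taken over the 14 alternatives run for each gene, the 8 that leave out 1 array included (13 for S100a8, which the filter on dim probe sets removed). A further quantile normalization left 484 calls, of which 62.4% were higher, against 69.5% for the values as deposited.

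**Figure D1:**
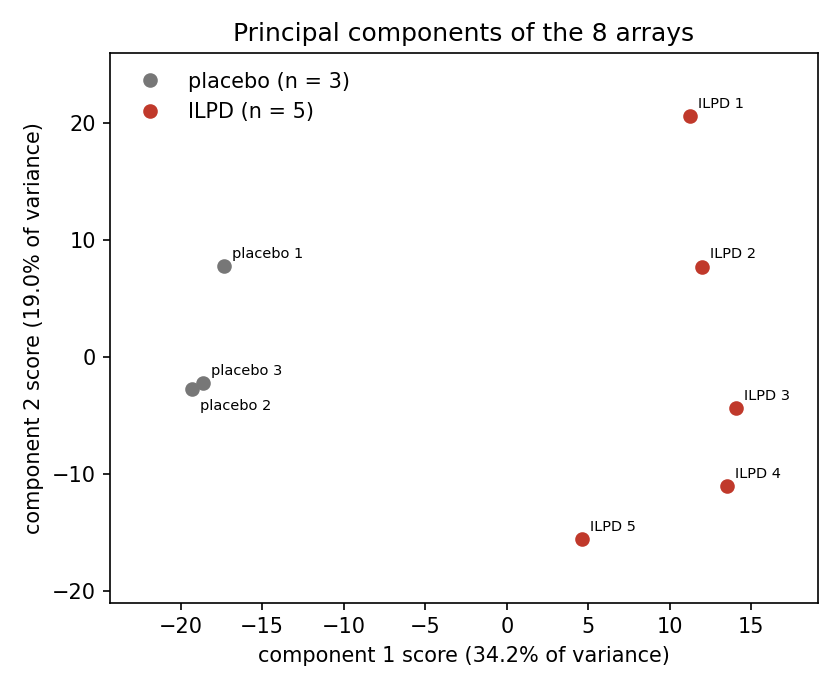
Scores of the 8 arrays on the first and second principal component of all log2 values, with the share of variance on each axis (placebo grey, ILPD red). The 3 placebo arrays lie below -17 on the first component and the 5 ILPD arrays above 4.

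Genes for protein chaperones were lower in the ILPD hearts. Of 29 measured members of the heat shock list, 18 fell and 0 rose (22 fell when adjusted over the list alone). Dnajb1, a cochaperone of the Hsp70 family (probe set 10810295), fell by 2.89 on the log2 scale (SE 0.33, limma adjusted p = 0.00332), from 12.06 ± 0.69 (SD, n = 3) to 9.17 ± 0.50 (SD, n = 5), a 7.39-fold difference. Hsph1, a nucleotide exchange factor of Hsp70 (probe set 10756343), fell by 2.22 (SE 0.20, adjusted p = 0.00108), from 11.62 ± 0.34 to 9.40 ± 0.34. Hsp90aa1, the inducible cytosolic Hsp90, fell by 1.35 (SE 0.12), and its cochaperones Stip1 and Chordc1 fell by 1.27 and 1.26 (SE 0.07 for both, adjusted p = 9.42e-05 for both). Hspb1, a small heat shock protein, fell by 0.98, and Hspd1, the mitochondrial chaperonin, fell by 0.80, while a dimmer probe set of Hspd1 gave -0.38 and did not pass (adjusted p = 0.0808). The calls of these 7 genes held in all 14 alternatives. Dnaja1 (-1.31) and Bag3 (-0.74) also fell, but their calls were lost without placebo array 2 or 3, with an adjusted p of up to 0.0669 and 0.0517, and that of Hspa8 (-0.38) was lost after cyclic loess normalization (0.142). Hsf1, the transcription factor of the heat shock response, differed by -0.21 and did not pass the test (adjusted p = 0.195). The list as a whole was shifted downward, with a median of -0.48 (camera adjusted p = 1.15e-24); this call was lost with adjusted p = 0.176 with an estimated correlation, and 10 members fell without placebo array 2 or without placebo array 3.

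**Figure D2:**
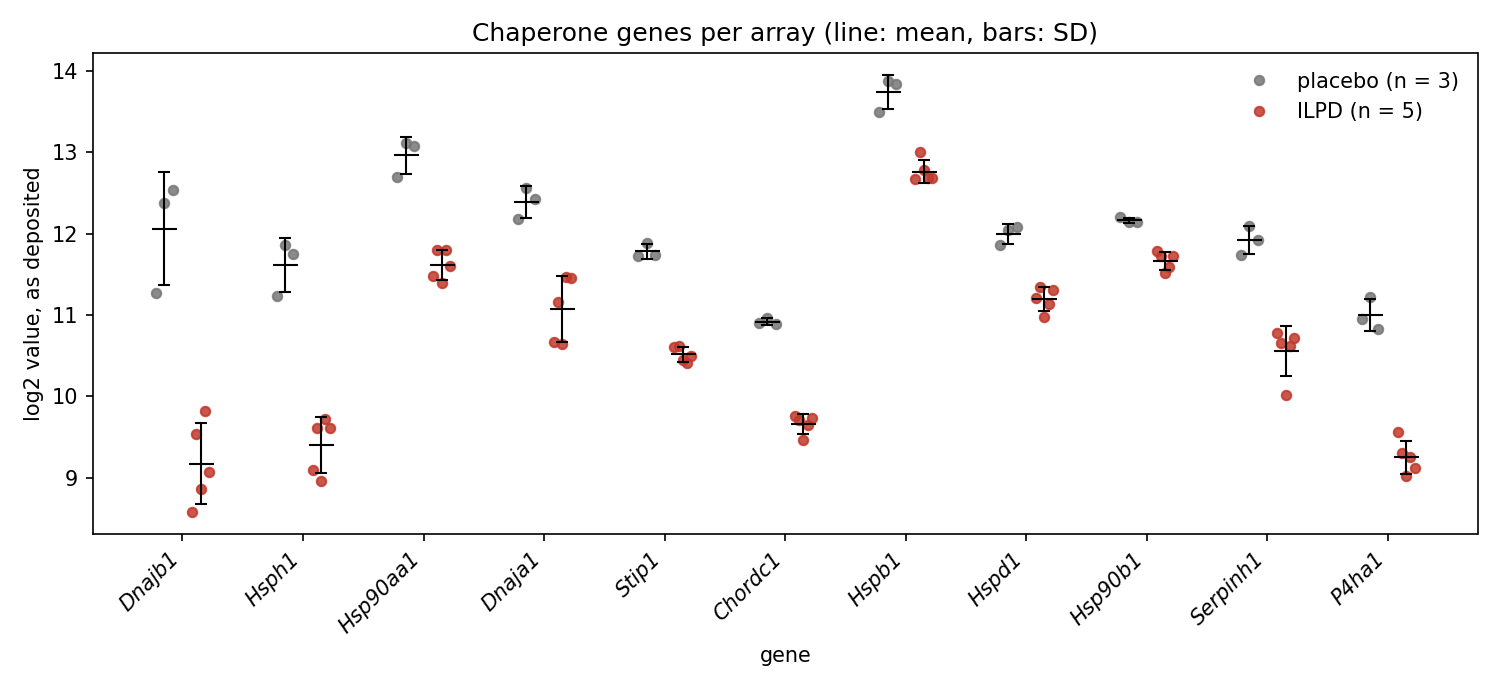
Deposited log2 value of 11 genes for chaperones and collagen processing on each array, placebo grey (n = 3) and ILPD red (n = 5), with the mean as a line and the SD as bars. For each gene the ILPD arrays lie below the placebo arrays, with a mean difference of -2.89 for Dnajb1 and -0.50 for Hsp90b1.

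Some genes for proteins of the endoplasmic reticulum fell too. Serpinh1, the collagen chaperone of that compartment (probe set 10723884), fell by 1.37 (SE 0.16, limma adjusted p = 0.00343). P4ha1, a subunit of the enzyme that hydroxylates collagen prolines (probe set 10931308), fell by 1.75 (SE 0.12, adjusted p = 0.000372), from 11.00 ± 0.20 (SD, n = 3) to 9.25 ± 0.20 (SD, n = 5). In the list for stress of the endoplasmic reticulum, 3 of 35 measured members fell and 2 rose (7 and 2 when adjusted over the list alone). Those that fell were the chaperones Hsp90b1 (-0.50), Hspa5 (-0.42) and Pdia4 (-0.64), and those that rose were the amino acid transporter Slc7a5 (0.97) and the folate enzyme Mthfd2 (0.41). The calls of Hsp90b1, Serpinh1 and P4ha1 held in all 14 alternatives. The others were lost without at least 1 array, reaching 0.0517 for Pdia4 (without placebo array 3), 0.101 for Slc7a5, 0.123 for Hspa5 and 0.135 for Mthfd2. The list was shifted downward with a median of -0.08 (camera adjusted p = 0.00706), which was -0.13 without placebo array 2, -0.14 without placebo array 3, -0.13 without ILPD array 4 and -0.14 without dim probe sets. That call was lost after quantile normalization (0.147), after cyclic loess (0.113) and with an estimated correlation (0.578).

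Several of the largest changes lay outside the heat shock list. Mat2a, which makes S-adenosylmethionine (probe set 10767001), rose by 1.31 (SE 0.11, limma adjusted p = 0.00108), from 11.34 ± 0.19 (SD, n = 3) to 12.66 ± 0.18 (SD, n = 5), and its other probe set gave 1.29. Rbm3, an RNA-binding protein known to rise in the cold (probe set 10932422), rose by 1.18 (SE 0.09, adjusted p = 0.000863), from 9.29 ± 0.09 to 10.47 ± 0.17. Srsf5, a splicing factor, rose by 1.12 (adjusted p = 0.0105), and Acer2, a ceramidase, rose by 1.29 (adjusted p = 0.00343). Rsrp1, an arginine- and serine-rich protein, fell by 1.48 (SE 0.08, adjusted p = 9.42e-05), and Ccdc117 fell by 1.35 (SE 0.09, adjusted p = 0.000214). These 6 calls held in all 14 alternatives, that of Srsf5 with an adjusted p of up to 0.04999. Lypd8l1 had the largest rise of a named gene under the rule, 1.48 (SE 0.25, adjusted p = 0.0183), a call lost without placebo array 2 or 3 (up to 0.0809).

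Some genes of inflammation rose in the ILPD hearts. Of 32 measured cytokines and targets of NF-kB, 4 rose and 0 fell (14 rose when adjusted over the list alone), and 31 had a positive difference. Cxcl2, a chemokine that attracts neutrophils, rose by 1.26 (SE 0.24, limma adjusted p = 0.0291), Ccl3 by 0.83, Nfkbia, the inhibitor of NF-kB, by 0.71, and Ccl2, which attracts monocytes, by 0.64, from an already high 12.43 ± 0.09 (SD, n = 3). These 4 calls were each lost without several single arrays, placebo array 2 among them for all 4, with an adjusted p of up to 0.161. In the list of IL-6 and STAT3 responses, 3 of 27 rose (6 when adjusted over the list alone): the oncostatin M receptor Osmr by 1.03 (SE 0.11, adjusted p = 0.00203), the IL-1 receptor Il1r1 by 0.71 (SE 0.08, adjusted p = 0.00343) and Socs1 by 0.46, the last lost without 5 single arrays (up to 0.113). Osmr and Il1r1 held in all 14 alternatives. Il6 (0.66, adjusted p = 0.380) and Socs3 (0.16, adjusted p = 0.686; 0.0297 without ILPD array 5) did not pass. The camera shifts of both lists were upward, with medians of 0.50 (adjusted p = 2.55e-08) and 0.16 (adjusted p = 3.32e-05), each with adjusted p = 0.469 with an estimated correlation; the second median was 0.25 after cyclic loess.

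Some interferon-stimulated genes rose as well. Of 29 measured members, 7 rose and 0 fell (8 rose when adjusted over the list alone), and 20 had a positive and 9 a negative difference. Ifit2 rose by 0.82 (SE 0.08, limma adjusted p = 0.0011), and Irf9, a subunit of the interferon-activated transcription complex, by 0.62 (SE 0.06, adjusted p = 0.00108); both held in all 14 alternatives. Ifit3 (0.87), Oasl (0.71), Rtp4 (0.65), Oas1a (0.64) and Mx1 (0.54) rose too, with calls lost without placebo array 2 or 3 and other arrays (adjusted p of up to 0.170 for Oasl). The list had a median of 0.21 (camera adjusted p = 0.000447; adjusted p = 0.578 with an estimated correlation), which was 0.13 without ILPD array 1 (camera adjusted p = 0.00704). In the list of glucocorticoid responses, Sult1a1 (0.76) and Nfkbia rose among 23 members (8 when adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.000918; adjusted p = 0.469 with an estimated correlation). The call of Sult1a1 was lost without any of 5 arrays, placebo arrays 2 and 3 among them (up to 0.112).

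**Figure D3:**
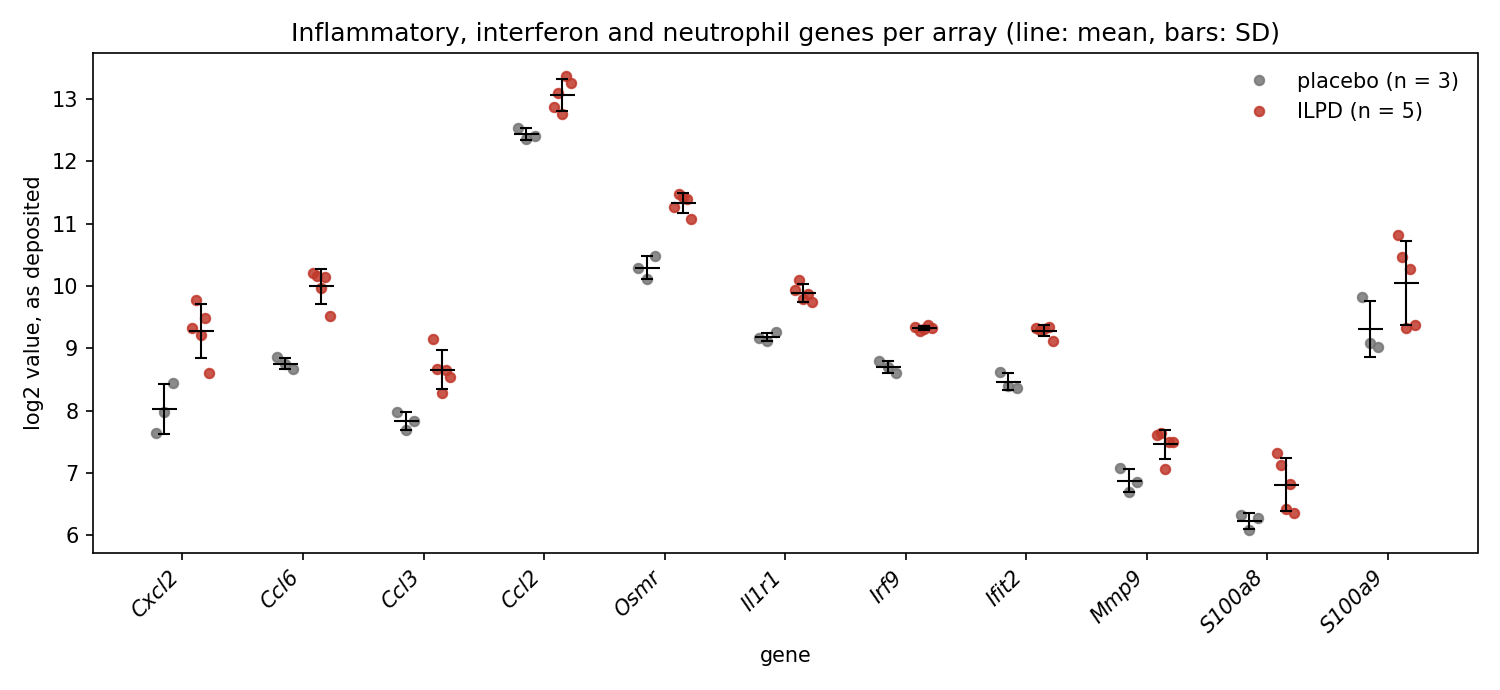
Deposited log2 value of 11 inflammatory, interferon and neutrophil genes on each array, placebo grey (n = 3) and ILPD red (n = 5), with the mean as a line and the SD as bars. Osmr, Il1r1, Irf9 and Ifit2 show ILPD arrays well above placebo, while Mmp9 and S100a9 overlap between the groups.

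Few markers of white blood cells passed the test. The neutrophil list had the highest median, 0.58 over 23 members, of which 21 had a positive difference. Its camera adjusted p was 1e-05, and 0.469 with an estimated correlation. Over all probe sets 1 member rose (11 rose and 1 fell when adjusted over the list alone). That member was the gelatinase Mmp9 (0.58, limma adjusted p = 0.0466), whose groups overlapped and whose call was lost in 12 of 14 alternatives. Mmp8 (1.32, adjusted p = 0.0511), Il1r2 (1.17, 0.0683), S100a9 (0.74, 0.297) and S100a8 (0.58, 0.176) did not pass, though Mmp8 did in 4 and Il1r2 in 2 of 14 alternatives (lowest 0.0280 and 0.0398). The list's median was 0.88 without dim probe sets. Ncf1, a subunit of the phagocyte oxidase, was the member that fell when adjusted over the list alone (-0.42, adjusted p = 0.0434 there and 0.190 over all probe sets), with no overlap between groups. Among the 10 largest rises under the naming rule, outside that list, Slc11a1, a metal transporter of phagocytes (probe set 10924286), rose by 1.17 (SE 0.10, adjusted p = 0.000932), and the chemokine Ccl6 by 1.24 (SE 0.14, adjusted p = 0.00335), both in all 14 alternatives. Clec7a, the receptor for fungal glucans (1.22), and Lilrb4 (1.11) rose with calls lost without placebo array 2 or 3 and others (up to 0.0913 and 0.134). In the monocyte and macrophage list 1 of 26 rose, Cx3cr1 (0.76, lost without any of 4 arrays, up to 0.123), and Ccr2 did not pass (1.21, adjusted p = 0.0624), though it did in 3 of 14 alternatives (lowest 0.0254). The list missed the threshold (camera adjusted p = 0.0516) but passed without placebo array 1 (0.00725), placebo array 3 (0.0207), ILPD array 3 (0.0155) or ILPD array 4 (0.0123), without dim probe sets (0.0493), after quantile normalization (0.00127) and after cyclic loess (0.00155). In the T and NK cell list 1 of 22 rose, Klrd1 (0.52, lost without any placebo array, up to 0.103), with a median of 0.09 (camera adjusted p = 0.000918; adjusted p = 0.469 with an estimated correlation), which was 0.06 without placebo array 2, 0.15 without placebo array 3 and 0.05 after quantile normalization.

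Lists of energy metabolism and contraction had slightly negative medians as deposited. Their calls depended on the normalization and on the correlation assumed between genes. Most members of these lists had a small negative difference as deposited. These were 49 of 49 for oxidative phosphorylation, 20 of 20 for the TCA cycle and 21 of 21 ventricular cardiomyocyte markers. They were 54 of 57 ribosomal proteins, 29 of 31 proteasome subunits and 22 of 28 for glycolysis. Single members seldom passed: 1 of 49 for oxidative phosphorylation (Atp5mc1, -0.27; 0 when adjusted over the list alone), 0 of 20 for the TCA cycle (9 fell when adjusted over the list alone), 0 of 27 for fatty acid oxidation, 0 of 27 for calcium handling (10 fell when adjusted over the list alone), 0 of 57 ribosomal proteins and 0 of 31 proteasome subunits. Glycolysis had 1 fall, the enzyme Aldoa (-0.27), and 1 rise, the lactate exporter Slc16a3 (0.84), among 28 (10 fell and 1 rose when adjusted over the list alone), and the ventricular cardiomyocyte markers 1 fall, Tnnc1 (-0.37), among 21 (8 when adjusted over the list alone). Esrrg, a nuclear receptor that drives mitochondrial genes, fell by 0.37 in the mitochondrial biogenesis list. All 5 calls were lost without placebo array 2 or 3 and reached, over the alternatives, an adjusted p in limma between 0.0938 for Esrrg and 0.565 for Atp5mc1. List medians lay between -0.23 for glycolysis and -0.10 for the proteasome, with camera adjusted p from 6.8e-15 to 0.00227 over the 10 lists, the permeability transition list included. With an estimated correlation none passed, the lowest adjusted p being 0.469. Single arrays moved some medians by over 1.5 times: fatty acid oxidation to -0.08 and the proteasome to -0.06 without placebo array 1, and the proteasome to -0.05 and mitochondrial biogenesis to -0.09 without ILPD array 4. After cyclic loess normalization, added after the data were seen, none of the 10 passed (lowest adjusted p 0.0880), and the medians ran from -0.09 to 0.04. Brighter probe sets were lower in ILPD in general: the median difference was 0.06 for probe sets with a mean log2 value from 7 to 8, and -0.14 above 12.

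**Figure D4:**
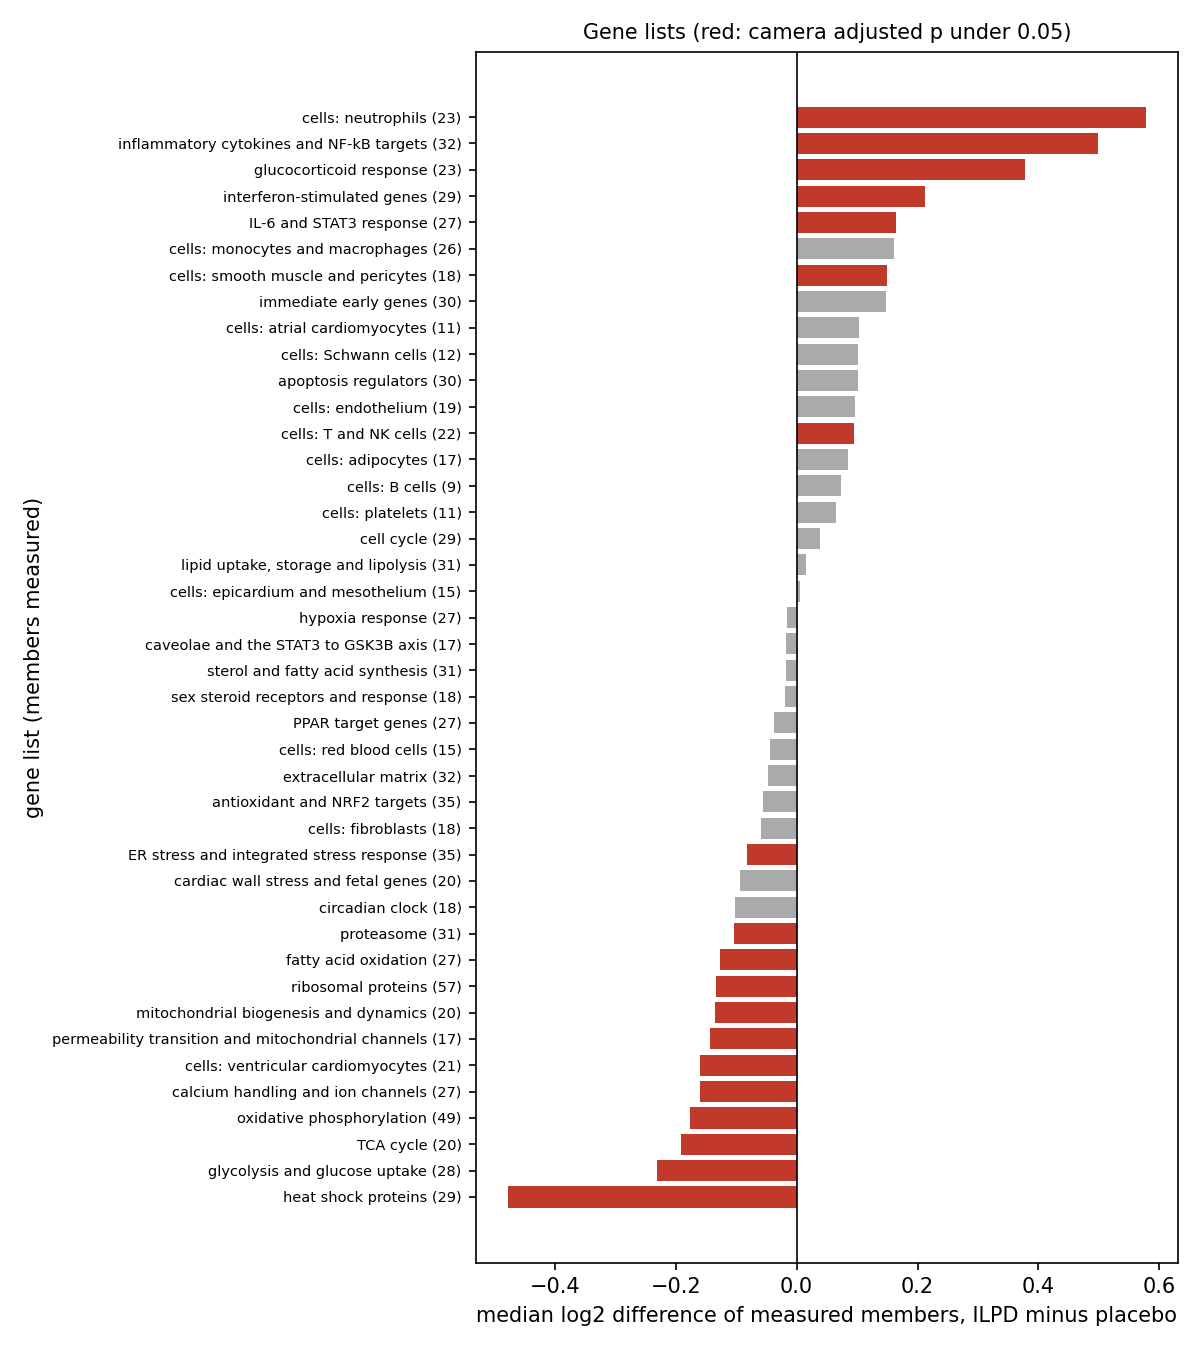
Median log2 difference, ILPD minus placebo, of the measured members of 42 gene lists, with the number of measured members in brackets and red bars for a camera adjusted p under 0.05. The neutrophil list lies highest at 0.58 and the heat shock list lowest at -0.48, and the red bars between -0.10 and -0.23 lose their calls after cyclic loess normalization.

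Over the 42 lists, camera called 19, of which 7 were higher and 12 lower in ILPD. With an estimated correlation 0 lists were called, and fry, which asks whether a list moves on balance in 1 direction, called the heat shock list alone (adjusted p = 0.00171). Of the 56 ways to part the 8 arrays into 5 and 3, 7 gave at least 19 lists. Each split other than the real one called lists too, from 4 to 21. A camera call at the preset correlation therefore does not by itself mark a difference between ILPD and placebo. No other split gave any probe set past the threshold in limma, and the real split had 5271 probe sets at an unadjusted p under 0.05 against at most 3513 in the others. Of 942 measured list genes, 35 rose and 31 fell.

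The caveolae list, with STAT3 and GSK-3beta, was fixed with knowledge of the study's own interest in these genes, so it is not independent evidence of a direction. Of its 17 members 1 rose, Cav2, a caveolin, by 0.70 (SE 0.11, limma adjusted p = 0.0127), from 9.22 ± 0.24 (SD, n = 3) to 9.92 ± 0.13 (SD, n = 5); adjusted over the list alone, 1 rose as well. The call was lost without placebo array 2 or 3 (up to 0.0669). Cav1 (0.26, adjusted p = 0.246), Cav3 (-0.27, 0.341), Stat3 (0.01, 0.978) and Gsk3b (-0.27, 0.163) did not pass. The list was not shifted (camera adjusted p = 0.471). Only transcripts were measured on these arrays, so the values do not speak to the activity of the proteins. Of the permeability transition genes, 0 of 17 passed, and 1 fell when adjusted over the list alone. Ppif, cyclophilin D, differed by -0.13 (limma adjusted p = 0.408). Vdac1 differed by -0.32 (0.0507, running from 0.0365 to 0.255 over the alternatives). Its other probe sets gave -0.20 (0.109) and -0.21 (0.144).

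Lipid genes showed few changes. In the list for lipid uptake and storage 2 of 31 rose, the fatty acid binding protein Fabp4 by 0.82 (limma adjusted p = 0.0173) and the acyl-CoA synthetase Acsl4 by 0.60 (0.0172), and 4 rose when adjusted over the list alone. Msmo1, of sterol synthesis, rose by 0.38 as 1 of 31 in its list (3 over the list alone), and Vnn1 fell by 0.34 as 1 of 27 PPAR targets. Their calls were lost without placebo array 3, and for Acsl4, Msmo1 and Vnn1 also without placebo array 2, with an adjusted p of up to 0.160. Pdk4 (-0.21, adjusted p = 0.322), Ucp3 (0.72, 0.232), Angptl4 (0.95, 0.206), Cpt1b (-0.17, 0.264) and Cd36 (0.04, 0.861) did not pass. Without placebo array 3 the difference was 0.406 for Ucp3 and 0.407 for Angptl4. The camera test called none of these 3 lists (adjusted p = 0.544, 0.714 and 0.503), but it called the lipid uptake list and the PPAR targets as higher after quantile normalization (0.0138 and 0.0168) and after cyclic loess (0.0145 and 0.00956).

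A few genes of cell death and hypoxia changed, in both directions. Among 30 apoptosis regulators 2 rose and 2 fell (6 and 3 when adjusted over the list alone). Casp8, an initiator caspase, fell by 0.78 (SE 0.13, limma adjusted p = 0.0163), and Mcl1, which restrains apoptosis, by 0.54 (SE 0.08, adjusted p = 0.0102), although a much dimmer probe set of Mcl1 gave 0.03. Ripk1 rose by 0.51 and Pmaip1, which counters Mcl1, by 0.41. All 4 calls were lost without placebo array 2 (adjusted p of up to 0.126 over the alternatives). Of 27 hypoxia genes 2 rose and 1 fell, as when adjusted over the list alone. Ndrg1 rose by 0.90 (SE 0.12, adjusted p = 0.00613) in all 14 alternatives, Bhlhe40 rose by 0.52 (lost without placebo array 1 or 2, up to 0.0701) and P4ha1 fell. Neither list was shifted (camera adjusted p = 0.241 and 0.639).

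Markers of other cells and the remaining lists gave few calls. Endothelium had 3 rises of 19 (7 rose and 1 fell when adjusted over the list alone), namely Egfl7 (0.60), Robo4 (0.43) and Fabp4, with a camera adjusted p of 0.0580; the list passed without placebo array 2 (0.0152), ILPD array 1 (0.0204) or ILPD array 5 (0.0180), without dim probe sets (0.0493), after quantile normalization (0.000980, median 0.19 against 0.10) and after cyclic loess (0.00154, median 0.21). Smooth muscle and pericytes had 1 of 18, the potassium channel Kcnj8 (0.64), with a camera adjusted p of 0.0310 that rose to 0.118 without ILPD array 4, 0.102 without placebo array 1 and 0.0831 without ILPD array 5, and adjusted p = 0.584 with an estimated correlation. Fibroblasts had 1 of 18, Scara5 (0.34), with a camera adjusted p of 0.398. The calls of these 4 genes other than Fabp4 were lost without placebo array 2 or 3 (limma adjusted p of up to 0.115). Of sex steroid genes 2 of 18 rose, Pgrmc1 (0.35; its other probe set gave 0.23 and did not pass, adjusted p = 0.211) and Gper1 (0.24), and Ncoa1 fell (-0.31); Gstm2 fell (-0.26) as 1 of 35 antioxidant genes. These 4 calls were lost in 9 to 12 of 14 alternatives, each of the placebo arrays among them. No member passed among 30 immediate early genes, where Fos (-0.02, adjusted p = 0.984) varied by an SD of 1.05 in placebo, and the list's camera adjusted p of 0.465 became 0.000256 without placebo array 3. Nor did Egr1, Nppa (-0.19), Nppb (-0.40), Hmox1 (-0.32), Hbb (-0.04), Per1 (0.45), Dbp (-0.25) or Bmal1 (0.27) pass. Over the alternatives, Nppa ran from -0.38 to 0.02, Nppb from -0.56 to -0.16 and Hbb from -0.31 to 0.14. Of 18 circadian clock genes 1 rose, Bhlhe40. Adjusted over that list alone, 2 rose and 4 fell, Per1 and Dbp among them. Lists for the circadian clock, matrix, wall stress, cell cycle, antioxidants, sex steroids, atrial cells, epicardium, B cells, red cells, platelets, adipocytes and Schwann cells were not shifted (camera adjusted p between 0.0679 and 0.787), though without placebo array 2 the Schwann cell (0.0356) and red cell (0.0438) lists passed, without ILPD array 1 the Schwann cell list again (0.0192), and without placebo array 1 the circadian list (0.0267). The median and the mean differed in sign for the PPAR targets (-0.04 and 0.06), sterol synthesis (-0.02 and 0.02), the matrix (-0.05 and 0.03) and the epicardium (0.01 and -0.01), and camera gave a downward direction for all 4.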

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

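The 5 ILPD arrays were searched for a single array far from the others, in 99 genes taken from the naming rule and in the array medians; chance alone would give about 5 cases in these 100 groups, and 6 were found. ILPD array 5 stood apart for Socs3 at a log2 value of 9.91 (the others 10.64 to 10.81), for Ifit2 at 9.12 (9.29 to 9.33), for Angptl4 at 9.59 (10.31 to 10.60) and for Aldoa at 13.81 (13.67 to 13.71). ILPD array 3 stood apart for Serpinh1 at 10.02 (10.62 to 10.77) and for Mmp9 at 7.07 (7.49 to 7.63).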

How the results depend on the processing

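Cyclic loess and the removal of the unnamed block were chosen after the data were seen. The 811 changed probe sets (564 higher, 247 lower) became 484 after quantile normalization (302 higher), 1756 at an adjusted p of 0.1 (1159 and 597), 342 with an unadjusted p under 0.05 and at least 1.5-fold (277 and 65), and 172 to 975 when 1 array was left out (116 to 600 higher, 56 to 375 lower). The trend and robust prior (666), dim filter (938), array weights (998), cyclic loess (562) and removal of the unnamed block (918) stayed within 1.5 times. After quantile normalization 422 of the calls were shared, and after cyclic loess 483. Of 42 lists, 19 were called, 12 after quantile normalization (8 of the 19 and 4 others), 12 after cyclic loess (8 and 4), 0 with an estimated correlation and 1 by fry. The list members past the threshold went from 66 to 42 after quantile normalization, to 157 adjusted over each list alone and to 19 to 100 without 1 array. Heat shock members that fell numbered 10 to 20 without 1 array, and, of 99 genes taken from the naming rule, those past the threshold numbered 26 to 66 without 1 array, against 70. Of these 70, 26 to 63 kept their call without 1 array, and 23 kept it over all 14 alternatives. The PPAR median turned from -0.04 to 0.057 after quantile normalization and 0.092 after cyclic loess, and after cyclic loess that of fatty acid oxidation turned from -0.13 to 0.0048 and of ventricular cardiomyocytes from -0.16 to 0.038; these methods remove differences that depend on intensity, and leaving out arrays lowers the sample number, while other causes were not tested.

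Replicate numbers 1 to 3 occur in both groups. After subtracting group means, arrays with the same number correlated across probe sets at r = 0.221, -0.0642 and -0.098. Pairs with different numbers ran from -0.165 to 0.247. These values do not settle whether the numbers pair the samples. With the replicate block, 459 probe sets passed (337 higher, 122 lower), and 20 lists against 19. Of these probe sets, 298 were shared with the main calls. Numbers 4 and 5 occur in ILPD alone, so with the block those arrays add nothing to the estimated group difference. The block therefore changes the arrays compared as well as the pairing. Of the 2 fits, only that with the block called the lists for lipid uptake (median 0.12, camera adjusted p = 0.0378), monocytes (0.14, 0.00344), the matrix (-0.10, 0.0139) and fibroblasts (-0.10, 0.0219), and only that without it called fatty acid oxidation (0.120 with it), the proteasome (0.294) and smooth muscle (0.327). The median of the IL-6 list was 0.29 and that of ribosomal proteins -0.04 with it. With it Il1r2, Ccr2, Ucp3 and Per1 passed, and not every array correlated best with its own number. No detection signal was used here, so what dim probe sets can show is not bounded.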

Other observations

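Of the tests below, those of intensity, of cell shares, of the neutrophil marker mean and of the count of list members were chosen after the results were seen. The following genes were also chosen after their values were seen. Clk1 and Clk4, kinases that phosphorylate splicing factors of the Srsf family, fell by 0.92 (SE 0.17, limma adjusted p = 0.0248) and 0.55 (SE 0.10, adjusted p = 0.0265). The SD of Clk1 was 0.46 in placebo and 0.14 in ILPD. Amd1, which uses S-adenosylmethionine to make polyamines, rose by 0.84 (SE 0.12, adjusted p = 0.0106). When 1 array was left out, Clk1 and Amd1 passed in 6 of 8 cases and Clk4 in 3 (adjusted p of up to 0.0630, 0.0571 and 0.0636), and Clk1 did not pass after cyclic loess (0.0595). Cirbp, a cold-inducible RNA-binding protein like Rbm3, differed by 0.45 and did not pass (adjusted p = 0.180). After subtracting group means, Cirbp correlated with the mean of the heat shock list at r = -0.246 (permutation p = 0.443). This relation, of a gene chosen after its values were seen, is 1 of the 3 relations adjusted together below.

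Chance is an unlikely source of the probe set count, but it is not excluded. Of the 56 splits of the 8 arrays, 1, the real one, gave 811 probe sets, and the highest other count was 0. The exact permutation p of 0.0179 is the smallest that 56 splits can give. A mixed split also places a real group difference inside its groups, which lowers its count. Splits of arrays cannot exclude a chance difference between animals either, since separate animals are not stated. The 18 heat shock members that fell and the 66 list members that changed also came from 1 of 56 splits each (highest other 0), but a split with 0 probe sets can give no member, so these counts add nothing to the first. Chance cannot be excluded for the count of lists either, since 7 of 56 splits gave at least 19 and the highest other gave 21.

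The fall of the chaperone genes was weighed against 3 explanations. After cyclic loess the heat shock median was still -0.41 (camera adjusted p = 4.77e-16), which argues against intensity as the whole source, although the list's call as deposited was lost with an estimated correlation (adjusted p = 0.176). The fall exceeded that of cardiomyocyte markers by -0.51 per array on average (exact two-sided permutation p = 0.0179, the smallest 56 splits can give). The size of that gap argues against a lower share of cardiomyocyte RNA as the whole source. Its p adds no support, since the shifts of both lists had been seen when the test was chosen. A difference in tissue temperature between hearts may lower chaperones and raise Rbm3, but after subtracting group means the correlation of Rbm3 with the heat shock mean over 8 arrays was r = -0.0467 (permutation p = 0.914, Benjamini-Hochberg 0.914 over 3 relations; rho = 0.119, p = 0.796; r = 0.729 without the 2 most distant arrays), so a temperature difference and the treatment cannot be told apart: such a difference could lie wholly between the groups. An effect of the treatment itself stays open as well.

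The small fall of the mitochondrial, ribosomal and contractile lists may come from an intensity-dependent difference between arrays, since the median over the 10 lists was -0.0141 after cyclic loess and none kept its call. Cyclic loess would also remove a true fall of abundant transcripts. For a lower share of cardiomyocyte RNA, markers of other cells should rise alike. Endothelial less fibroblast markers differed by 0.19 between groups (exact two-sided permutation p = 0.125), which cannot show whether either list rose. As deposited, the list medians were 0.10 for endothelium, 0.15 for smooth muscle and -0.06 for fibroblasts (camera adjusted p = 0.0580, 0.0310 and 0.398). A rise in all 3 was thus not seen, but the fibroblast list was not shifted downward either, and that explanation stays undecided.

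Whether more neutrophil RNA in the ILPD hearts could account for the rise of neutrophil, inflammatory and interferon genes stays undecided. The mean of the neutrophil markers was higher by 0.56 (exact two-sided permutation p = 0.0357), but this restates the shift that raised the question and is no support. Of the 23 markers, 21 had a positive and 2 a negative difference. Adjusted over the list alone, 11 rose and 1, Ncf1, fell, while over all probe sets 1, Mmp9, passed. Of well-known neutrophil genes, S100a8, whose probe set was dim, and S100a9 differed by 0.58 and 0.74 and Ncf1 by -0.42. None of these 3 passed limma's test over all probe sets. Within groups the interferon mean followed the neutrophil mean over the 8 arrays (r = 0.799, permutation p = 0.0292; rho = 0.690, p = 0.0764; r = 0.803 without the 2 most distant arrays), but not after Benjamini-Hochberg adjustment over 3 relations (0.0875). Induction in resident cells would give the same co-variation and stays open, and no count of cells was used here.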
